A study of Homo sapiens with 2 samples.

How the data were processed

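Gene expression was measured on Affymetrix arrays hybridised with biotin-labelled total RNA from 2 cultures of the head-and-neck squamous carcinoma cell line OECM-1, with 1 array per culture. The parental culture received PBS, the solvent control. The resistant culture was selected with cetuximab, an antibody that binds the extracellular part of the epidermal growth factor receptor (EGFR), at 300 µg/ml for 4 weeks and then at 1000 µg/ml until passage 30, per the labels' protocols; the series text puts it at more than 30 passages. The labels do not say whether the antibody was in the medium when the cells were harvested.

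The deposited table held 1 value per probe set and array for 54675 probe sets, of which 62 were control probe sets. The values were made by the authors with RMA (background correction, normalization between arrays and a summary per probe set), per the submitters' processing notes; the software, its version and the set of arrays normalized together are not given in the sources used here. The deposited values were read as log2 expression values. The base of the log is not given in the sources used here and was taken as 2 from the range of the values, which ran from 1.84 to 14.13 in the parental array and from 1.81 to 14.15 in the resistant array, with medians of 4.59 and 4.61. No centring per gene was visible in values of this range, and a single-colour array has no direction to settle. On both arrays, 3340 probe sets (6.11%) carried exactly the same value. RMA compresses differences of dim probe sets, so that a fold against a dim array is likely to be too small.

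Probe sets were named through the platform annotation supplied with the series. It gave 1 gene symbol to 41097 probe sets, several to 1801 and none to 11777, the controls included. Symbols were updated through the gene ID against the RefSeq gene table of assembly GRCh38.p14, which matched 41043 of the 41097 probe sets, and the other 54 kept the annotation's symbol. Only probe sets with 1 symbol were used, and no genome coordinates are given because the files name no build. Each of 19775 genes was represented by its probe set with the highest mean over both arrays. A gene was taken as measurable when its brighter array reached 4.60, the median of all probe sets over both arrays, which left 12648 genes. Detection calls were not used here, so this level is a fixed rule and not a measured background.

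With 1 array per group there is no replicate error, and no p-value was computed. Every difference below compares 2 arrays, not 2 conditions, and the number of arrays limits the precision. Differences are resistant minus parental on the log2 scale. A gene was counted as higher or lower when this difference was at least 1 in size, which is 2-fold. As a technical yardstick, the spread of the difference between probe sets of the same gene was computed over the 6159 genes with 2 or more measurable probe sets; its pooled SD was 0.27, or 1.21-fold. That spread covers probe behaviour and transcript variants, and not the variation between cultures. When 200 of 12268 genes were given known shifts in simulated arrays with that noise, the size rule found 94.0% of the log2 shifts of 1.5, 100% of those of 3, and 2 genes that had not been shifted. This outcome follows from the noise put in, so it gives no count of false calls in the real arrays.

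The 43 gene lists, the size rule, the level filter, the rule for named genes and the processing alternatives were fixed before the data were examined. The lists held 1047 entries, of which 111 had no probe set with a single symbol and are not analysed here. For each list, the median difference of its measured genes was set against 10000 random lists of the same size matched on mean expression in 20 bins. The resulting percentile describes these 2 arrays and is no test of the conditions. The genes named are EGFR, the 12 highest and the 12 lowest measurable genes whose measurable probe sets all went the same way, every measured ERBB receptor and ligand, and up to 4 measurable members per list with the largest differences; 1 of the 12 lowest genes is not reported here. A gene named outside this rule is marked as chosen after its values were seen. A gene with 1 measurable probe set met the condition that its probe sets go the same way automatically. Alternatives were the mean over all probe sets of a gene, leaving out probe sets with the _x_at or _s_at suffix (whose probes can match several transcripts), no level filter or one at the 75th percentile (6.74), arrays centred on their medians, a lowess curve of the difference on the mean subtracted (span 0.3), and a difference of 1.5. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.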

Results

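The transcriptome of cetuximab-selected OECM-1 cells was compared with that of the parental line on 1 array each, to find genes that differ between resistant and parental cells. The 2 arrays correlated with r = 0.987 across all probe sets other than controls. The median difference over the 12648 measurable genes was 0.00, and their quartiles lay at -0.22 and 0.20. The differences below have no replicate check. The bacterial hybridisation controls, added to each labelled sample, differed by a median of 0.018 over 18 probe sets. The poly-A spike controls, added before labelling, were lower in the resistant array for 24 of 24 probe sets, with a median of -0.25. The 3′ minus 5′ difference of the GAPDH control probe sets was 0.25 in the parental and 0.15 in the resistant array, and that of ACTB was 0.70 and 0.57. Of 3 probe sets for 28S ribosomal RNA, the brightest was 0.57 higher in the resistant array, the next 0.86 higher, and the dimmest differed by -0.077.

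In the resistant array 227 genes were at least 2-fold higher and 278 at least 2-fold lower than in the parental array, together a small part of the 12648 measurable genes (1.79% and 2.20%). Differences of at least 4-fold were found for 28 higher and 61 lower genes. Among the higher genes, 100 had 2 or more measurable probe sets, and in 90 of these all probe sets were higher. Among the lower genes, all probe sets were lower in 115 of 136. All measurable probe sets were at least 2-fold apart in the gene's direction for 48 of the 100 higher and 52 of the 136 lower genes. The dimmer array lay below the level for 50 of the higher and 72 of the lower genes. A stricter difference of 1.5 left 79 higher and 108 lower genes.

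**Figure D1:**
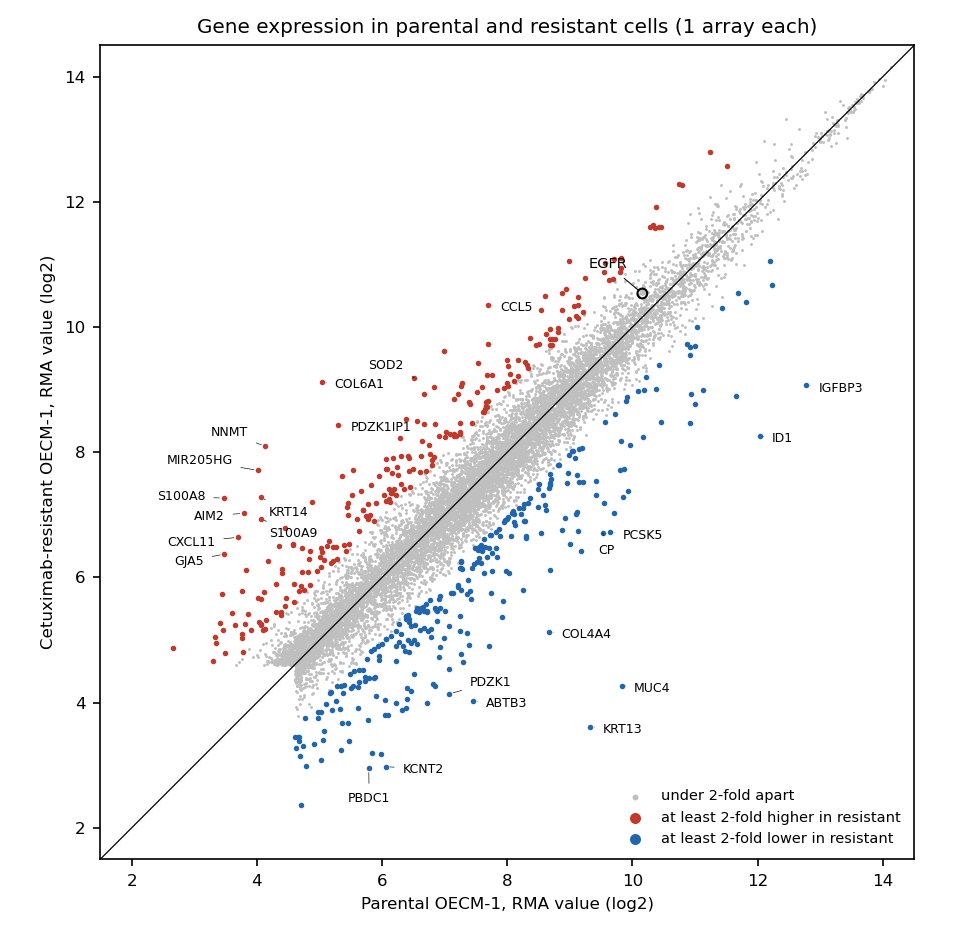
RMA values (log2) of the measurable genes in parental OECM-1 cells (x axis) and cetuximab-resistant OECM-1 cells (y axis), 1 array each, with 1 point per gene and the line of equal values. Red and blue points are genes at least 2-fold higher or lower in the resistant array; KRT13 and MUC4 lie farthest below the line, COL6A1 and NNMT farthest above it, and EGFR (circled) lies near it.

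The genes with the lowest values relative to the parental array included epithelial and secreted products. KRT13, a keratin of the suprabasal layers of mucosal epithelium, went from 9.33 to 3.61 (52.5-fold lower, 1 measurable probe set). MUC4, a membrane-bound mucin, went from 9.83 to 4.27 (47.0-fold lower), and its 4 measurable probe sets ranged from -5.56 to -0.66. ID1, an inhibitor of basic helix-loop-helix transcription factors, went from 12.03 to 8.26 (13.7-fold lower). IGFBP3, which binds insulin-like growth factors, went from 12.77 to 9.07 (13.0-fold lower), with differences of -3.91 and -3.70 in its 2 probe sets. The basement membrane collagen gene COL4A4 was 11.6-fold lower, and ABTB3 was 10.8-fold lower. The potassium channel gene KCNT2, the scaffold gene PDZK1, the proprotein convertase gene PCSK5, PBDC1 and CP, which encodes the copper-binding plasma protein ceruloplasmin, were 7.04 to 8.46-fold lower. Of these 11 genes, KRT13, MUC4, ABTB3, KCNT2, PDZK1 and PBDC1 lay below the level in the resistant array. KRT13, ID1 and PDZK1 had 1 measurable probe set each, so no other probe set could disagree. With all probe sets of a gene averaged, the differences of MUC4, COL4A4, PBDC1 and CP were -2.58, -2.27, -2.08 and -3.54.

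The genes with the highest values relative to the parental array included matrix, keratinocyte and inflammatory products. COL6A1, a chain of collagen VI, went from 5.04 to 9.12 (16.9-fold higher), but its 5 measurable probe sets ranged from 0.23 to 4.08, and the mean over all its probe sets differed by 0.92. Averaging all probe sets gave 2.37 for NNMT, 2.21 for S100A8 and 1.63 for GJA5, each described next by its brightest probe set. NNMT, which methylates nicotinamide, was 15.6-fold higher, and both of its measurable probe sets were higher. The calprotectin subunit genes S100A8 and S100A9 were 13.9-fold and 7.38-fold higher (S100A8 at 0.62 without the _x_at and _s_at probe sets). MIR205HG, the host gene of a microRNA expressed in squamous epithelium, was 12.9-fold higher, and the basal keratin gene KRT14 was 9.36-fold higher. AIM2, a sensor of cytosolic DNA, was 9.40-fold higher. PDZK1IP1 was 8.82-fold higher, the connexin gene GJA5 7.43-fold higher, and the chemokine genes CXCL11 and CCL5 were 7.68-fold and 6.35-fold higher. SOD2, the mitochondrial superoxide dismutase, was 6.39-fold higher. COL6A1, PDZK1IP1, SOD2 and CCL5 were above the level on both arrays, and the other 8 of these 12 genes were below it in the parental array. S100A8, S100A9, MIR205HG, KRT14, AIM2, GJA5 and SOD2 had 1 measurable probe set each, so no other probe set could disagree.

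EGFR, the target of the antibody, remained highly expressed, at 10.16 in the parental and 10.54 in the resistant array (difference 0.38, 1.30-fold higher). Its measurable probe sets did not go the same way. Of 6 measurable probe sets, 1 was 1.70 higher in the resistant array and 1 stood at -0.48, with the others between 0.049 and 0.56, so the direction for EGFR depended on the probe set. None of the 7 measurable ERBB receptors and ligands was 2-fold apart. The receptor gene ERBB2 differed by -0.25 and ERBB3 by -0.019, with the other sign when a lowess curve was subtracted. Among the ligands, HBEGF differed by -0.54, TGFA by -0.47, NRG1 by -0.21 and NRG2 by 0.063. ERBB4, EGF, EREG, BTC, NRG3 and NRG4 were below the level on both arrays, at differences of 0.17, 0.13, 0.20, 0.20, 0.28 and -0.42. The list's median difference over all 13 measured genes was 0.063, at percentile 69.5 of matched random lists, and -0.21 over the 7 measurable ones. The ligand genes AREG and EPGN, also on the list, had no probe set with a single symbol and were not analysed. With all probe sets of a gene averaged, ERBB3, ERBB4, EREG and NRG1 took the other sign.

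In the following lists of genes linked to signalling at and below the receptor, most measurable members were under 2-fold apart. Among 18 measurable adaptors and negative regulators of EGFR, only SOCS3, a feedback inhibitor of cytokine receptors, was 2-fold apart (3.12-fold higher, with probe sets from 0.25 to 1.64 and a mean of 0.86), and PTPN1, CBLB and SHC1 differed by 0.78, 0.68 and 0.67; the list's median was 0.011 (percentile 59.0), or -0.016 with the arrays centred on their medians. Of 22 genes that report ERK activity, 2 were at least 2-fold lower. These were FOS (2.68-fold lower), an immediate early transcription factor, and DUSP5 (2.58-fold lower), a nuclear ERK phosphatase. EGR1 and EPHA2 differed by -0.93 and -0.82, and the list's median was -0.058 (percentile 21.7). The separate list of immediate early genes, which also holds FOS, was lower as a group, with a median of -0.47 under every random list. None of the 14 measurable RAS, RAF and PI3K pathway genes was 2-fold apart. That list held 24 genes, and the others had no probe set with a single symbol, so they were not analysed. The median was 0.17 (percentile 96.3), or 0.056 with probe sets averaged, with RRAS at 0.95, NF1 at 0.83, HRAS at -0.65 and PIK3R3 at -0.51. Among 26 other receptor tyrosine kinases and ligands, VEGFC, a lymphangiogenic growth factor, was 2.18-fold higher, ROR1 2.86-fold lower (probe sets from -2.17 to -0.081) and the ephrin gene EFNB2 2.36-fold lower, and PDGFA differed by 0.99; the list's median was 0.11 (percentile 96.1). IGFBP3 was the only one of 4 measurable IGF binding proteins that was 2-fold apart. IGFBP6, IGFBP7 and IGFBP5 differed by 0.39, 0.24 and 0.18, and the list's median was 0.16 (percentile 90.7).

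Of the 43 gene lists, 8 lay above and 6 below the central 95% of matched random lists, where 2.15 would lie outside these bounds by chance if lists were independent. Lists share genes, and genes within a list are co-regulated, so this count is a description of the 2 arrays.

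**Figure D2:**
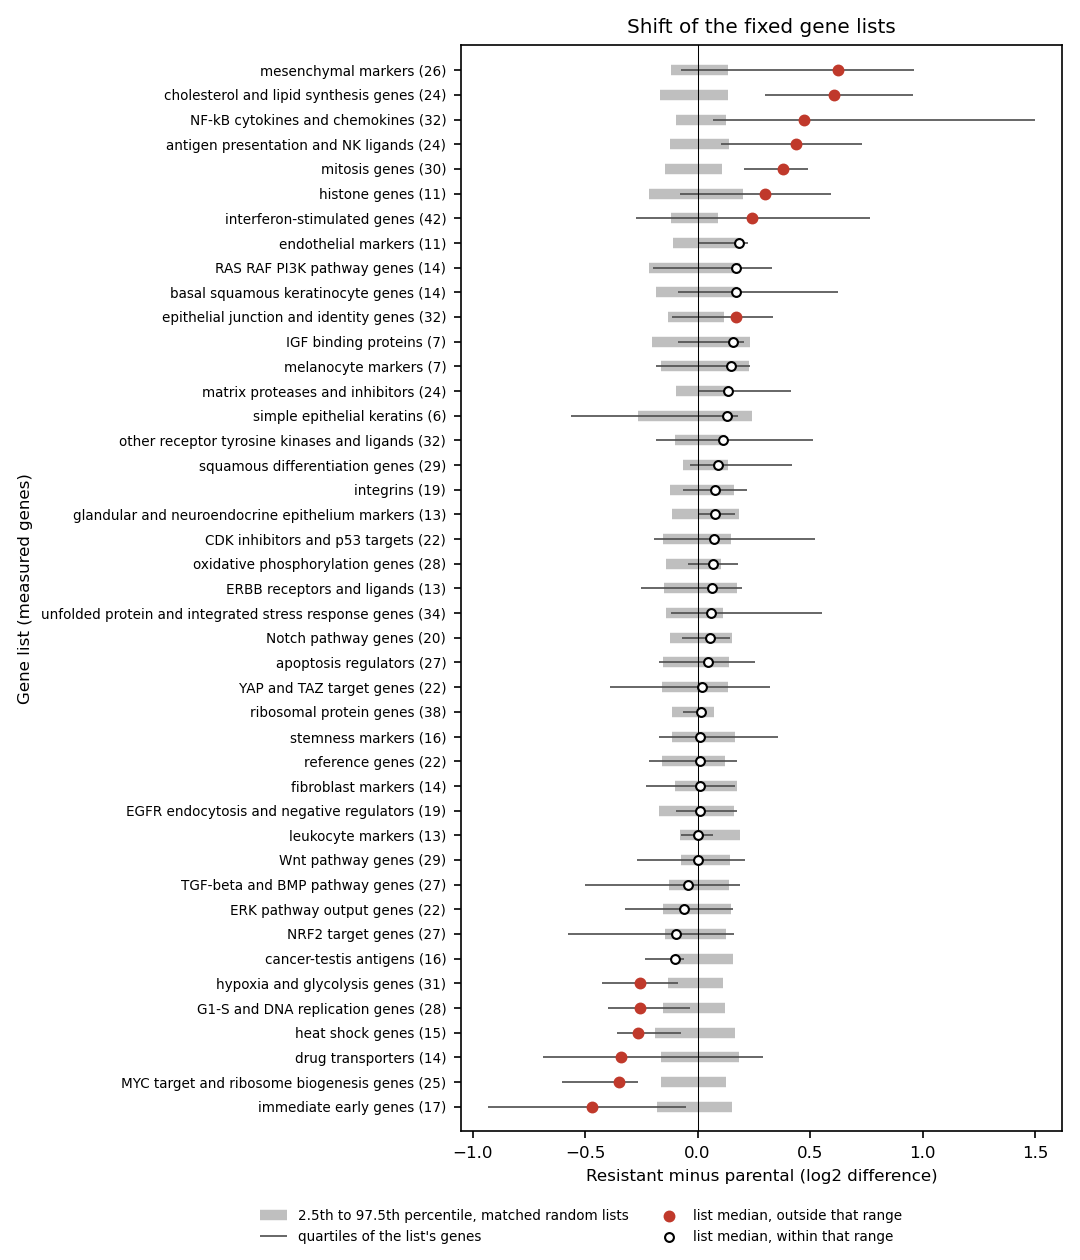
Median log2 difference (resistant minus parental, x axis) of each gene list (y axis, number of measured genes in brackets), with the quartiles of its genes (thin lines) and the central 95% of medians of 10000 expression-matched random lists (grey bars). Filled points lie outside the grey bar: 8 lists to the right, led by mesenchymal markers at 0.62, and 6 to the left, led by immediate early genes at -0.47.

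Inflammatory genes were higher in the resistant array. Of 26 measurable NF-kB-linked cytokine and chemokine genes, 14 were at least 2-fold higher, 2 were at least 2-fold lower and 10 lay between. With the arrays centred on their medians 13 were at least 2-fold higher, as IL6 went from 1.02 to 0.99. CXCL11 and CCL5, chemokines that attract T cells, SOD2, and the cytokine gene IL32 (log2 difference 2.32) were the highest. The 2 lower members, chosen after their values were seen, were LCN2, the iron-chelator carrier lipocalin 2 (2.95-fold lower), and TNFAIP2 (2.04-fold lower, at -0.78 with probe sets averaged). The list's median over all 32 measured members was 0.47, above every one of the 10000 random lists, and 1.03 over the measurable members. Markers of leukocytes did not accompany this difference: of 4 measurable leukocyte markers none was 2-fold higher, HCLS1 was 2.30-fold lower, CD79A, CORO1A and LAPTM5 differed by 0.34, -0.18 and 0.046, and the list's median was 0.00 (percentile 23.9).

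Antigen presentation genes and NK cell ligands were also higher, with 18 of 20 measurable genes above the parental value and a list median of 0.44, above every random list (0.21 without the _x_at and _s_at probe sets). TAP1, a subunit of the peptide transporter for MHC class I loading, was 2.06-fold higher and HLA-DMA 2.02-fold higher (1.98-fold with the arrays centred on their medians), and the immunoproteasome gene PSMB9 and the NK ligand gene MICB differed by 0.97 and 0.93. HLA genes share sequence, so a value for a single HLA gene is uncertain. Interferon-stimulated genes went both ways. Of 40 measurable genes, 4 were at least 2-fold higher and 4 at least 2-fold lower, and the list's median of 0.24 lay above every random list, but without the _x_at and _s_at probe sets it was 0.059 and lay at percentile 83.9. IFITM1, a membrane protein that restricts virus entry, was 2.94-fold higher. The other 3 higher members, HERC5, IFITM2 and EPSTI1 (2.64-fold, 2.08-fold and 2.08-fold), and the remaining lower one, XAF1 (2.16-fold), were chosen after their values were seen; with probe sets averaged EPSTI1 and XAF1 differed by 0.73 and -0.60. Without the _x_at and _s_at probe sets IFITM1 and IFITM2 were not measured, and whether they are separate observations was not tested. SAMD9 and SAMD9L, which are neighbouring antiviral genes, were 5.90-fold and 4.31-fold lower, and IFI44L was 4.23-fold lower.

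Markers of mesenchymal cells were higher as a group, with a median of 0.62 that exceeded every random list. Of 25 measurable markers, 5 were at least 2-fold higher and none was 2-fold lower. Besides COL6A1, the matrix glycoprotein gene TNC was 4.63-fold higher, the smooth muscle actin gene ACTA2 4.54-fold higher and the matrix protein gene SPARC 3.15-fold higher; CALD1, chosen after its values were seen, was 2.90-fold higher. With all probe sets averaged ACTA2 differed by 0.72 and TNC by 1.0. ACTA2 was then under 2-fold, and so was COL6A1. Epithelial junction and identity genes were not lower as a group. Their median was 0.17 (percentile 99.7), 1 of 31 measurable genes was at least 2-fold higher (CLDN1, a tight junction claudin, 2.52-fold) and 1 at least 2-fold lower (ELF3, an epithelial transcription factor, 2.27-fold, at -1.77 with probe sets averaged), and DSC3 and PRSS8 differed by 0.92 and 0.90. Of 7 measurable fibroblast markers none was 2-fold higher and LUM was 5.04-fold lower (-1.14 with probe sets averaged, and 0.061 without the _x_at and _s_at ones). FAP, FBLN1 and THY1 differed by 0.83, -0.76 and -0.45, THY1 with the other sign when probe sets were averaged. The list's median was 0.012 (percentile 35.0), or -0.015 with the arrays centred and -0.016 with a lowess curve subtracted. Among 18 measurable matrix proteases and inhibitors, the collagenase gene MMP1 was 2.47-fold higher, and SERPINE2, TIMP4 and MMP2 differed by 0.86, -0.80 and 0.70; the median was 0.14 (percentile 96.8). No integrin of 13 was 2-fold apart, with ITGA2, ITGB4, ITGB8 and ITGA5 at 0.78, 0.71, 0.64 and 0.43 and a list median of 0.079 (percentile 79.6).

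Keratinocyte genes differed strongly in single members and in both directions. Of 14 measurable basal keratinocyte genes, KRT14 and KRT16 (3.02-fold) were higher, KRT15 was 3.79-fold lower, and TRIM29 differed by 0.81. Of 14 measurable differentiation genes, 4 were at least 2-fold higher, S100A8 and S100A9 among them as well as CSTA and SERPINB3 (3.58-fold and 3.36-fold, chosen after their values were seen), and 2 were at least 2-fold lower, namely KRT13 and its pairing partner KRT4 (4.53-fold, at -1.02 with probe sets averaged). The medians of both lists, 0.17 and 0.093, lay within the range of random lists (percentiles 96.9 and 89.8). KRT80, placed in the list named simple epithelial keratins, was 2.13-fold lower, and KRT19, KRT7 and KRT18 differed by -0.79, 0.19 and 0.16. The median of that list was 0.13 (percentile 87.2) and -0.30 without the _x_at and _s_at probe sets. Among 7 measurable glandular and neuroendocrine markers, AGR2, a disulfide isomerase of mucus-secreting cells, was 6.77-fold lower (-1.91 with probe sets averaged), while MUC1, TFF3 and MUC5AC differed by 0.94, 0.19 and 0.15, and the list's median was 0.078 (percentile 72.2).

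Genes of cholesterol and lipid synthesis were higher in the resistant array. Of 24 measurable genes, 23 were above the parental value, 6 were at least 2-fold higher and none was 2-fold lower, and the median of 0.61 exceeded every random list. STARD4, a sterol carrier, was 3.84-fold higher. SCD, the stearoyl-CoA desaturase, MSMO1, a sterol oxidase, and HMGCS1, which makes the precursor of mevalonate, were 2.48-fold, 2.44-fold and 2.44-fold higher. Hypoxia and glycolysis genes were lower by smaller amounts, with 24 of 31 below the parental value and a median of -0.25 (percentile 0.03; -0.16 without the _x_at and _s_at probe sets). In this list PFKFB3, an activator of glycolysis, was 2.18-fold lower and the aldolase gene ALDOC 2.30-fold higher, and DDIT4 and PDK1 differed by -0.97 and -0.88. Oxidative phosphorylation genes had a median of 0.070 (percentile 92.6) and no member 2-fold apart, with SDHA, ATP5PB, NDUFV1 and COX5B at 0.51, -0.36, 0.35 and 0.35.

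Lists of proliferation genes went both ways. Of 30 mitosis genes, 27 were above the parental value, none was 2-fold apart, and the median of 0.38 exceeded every random list. The kinase gene AURKB, the kinesin gene KIF20A, UBE2C and PTTG1 differed by 0.64, 0.64, 0.56 and 0.56. Of 28 DNA replication genes, 22 were below the parental value, with a median of -0.25 (percentile 0.05); CLSPN, which relays replication stress, was 2.17-fold lower (-0.71 with probe sets averaged), and CCNE2, CDC45 and CDC6 differed by -0.75, -0.58 and -0.52. MYC target and ribosome biogenesis genes were below the parental value in 23 of 25 cases, with a median of -0.35 that lay under every random list; ODC1, which starts polyamine synthesis, was 2.36-fold lower, and UTP20, PUS7 and POLR1B differed by -0.96, -0.81 and -0.65. Histone genes had a median of 0.30 (percentile 99.8), with H3C2 2.12-fold higher and H2AC6, H4C8 and H1-2 at 0.80, -0.64 and 0.60.

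Immediate early genes were lower, with 13 of 17 below the parental value, 4 of them at least 2-fold, and a median of -0.47 under every random list. FOSB was 4.27-fold lower, EGR3 3.89-fold lower, FOS 2.68-fold lower and ATF3 2.44-fold lower. Drug transporters were lower as a group (median -0.34, percentile 0.05), with 3 of 11 measurable genes at least 2-fold lower and none 2-fold higher. These were ABCB1, the multidrug efflux pump P-glycoprotein (3.13-fold), ABCC4 (2.59-fold) and ABCC3 (2.06-fold), and ABCG2 differed by -0.70; ABCB1 and ABCC4 were below the level in the resistant array. With probe sets averaged ABCB1, ABCC4 and ABCC3 differed by -0.93, -0.57 and -0.70, all under 2-fold. Heat shock genes had a median of -0.26 (percentile 0.50), which was -0.10 and at percentile 11 when all probe sets of each gene were averaged, and -0.42 without the _x_at and _s_at probe sets. HSPA6 was 2.74-fold lower and the small heat shock gene CRYAB 2.29-fold higher, and HSPH1 and HSPB1 differed by -0.85 and 0.66.

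**Figure D3:**
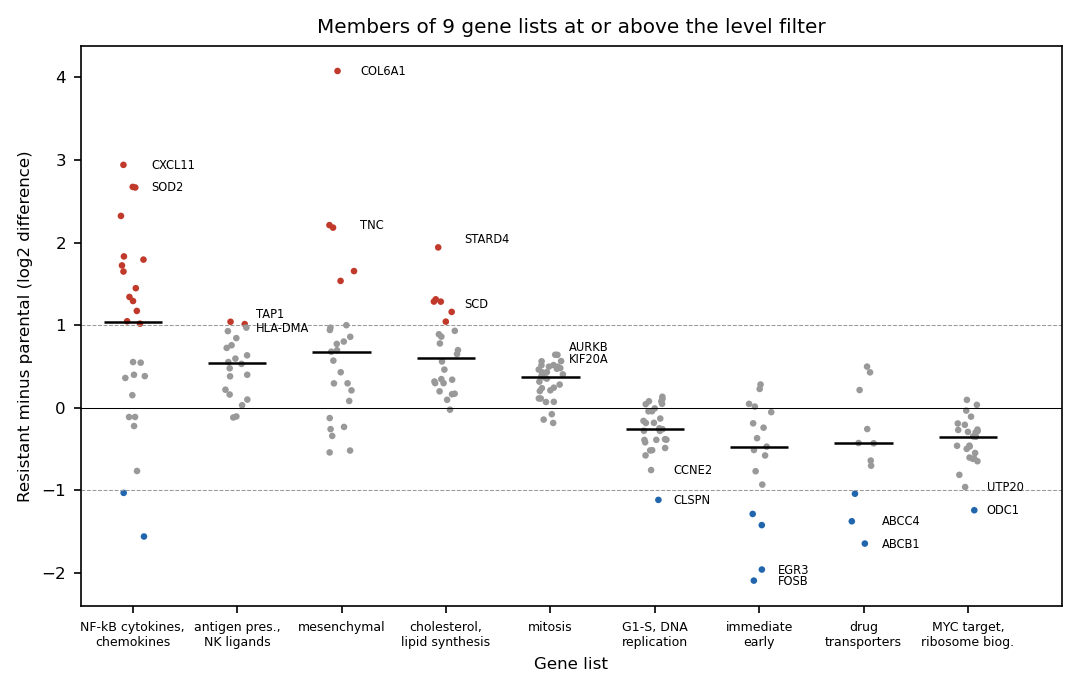
Log2 difference (resistant minus parental, y axis) of each measurable member of 9 gene lists (x axis), with 1 point per gene, the median of the points shown as a black bar and dashed lines at a 2-fold difference. Members of the NF-kB list reach 2.94 (CXCL11) with 14 above the upper dashed line, while the mitosis genes lie within a narrow band that does not reach it.

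In further lists the median lay within the range of random lists but single members were far apart. Among 23 measurable TGF-beta and BMP pathway genes, ID1, ID2 (5.07-fold) and the inhibitory SMAD6 (2.96-fold, with a second probe set at 0.23) were lower, as was BMP4 (2.02-fold, or 1.98-fold with a lowess curve subtracted, chosen after its values were seen), and INHBA, a subunit of activin, was 2.04-fold higher; the median was -0.042 (percentile 20.4). Averaging probe sets gave -0.44 for SMAD6 and -1.66 for ID2. The aldo-keto reductase genes AKR1C1, AKR1C2 and AKR1C3, which act on steroids and carbonyls, were 6.73-fold, 5.48-fold and 3.59-fold lower; they are near-identical in sequence, so the value of each one is uncertain, and AKR1C1 and AKR1C2 differed by -1.32 and -1.69 with probe sets averaged, AKR1C2 by -0.13 without the _x_at and _s_at ones. With ABCC3 they were the only members of 26 measurable NRF2 targets that were 2-fold apart, and the list's median was -0.098 (percentile 9.06). Of 21 CDK inhibitors and p53 targets, the death receptor gene FAS was 3.42-fold higher in the chosen probe set and higher in all 4 (0.56 without the _x_at and _s_at probe sets), TP53INP1 3.36-fold lower (with a second probe set at 0.063), GDF15 2.43-fold lower and TP53I3 2.42-fold lower; GADD45A, chosen after its values were seen, was 2.11-fold higher, and the median was 0.073 (percentile 82.5). With probe sets averaged TP53INP1 and GDF15 differed by -0.56 and -0.57, which ends both calls. Among YAP and TAZ targets, LATS2 and RBMS3 were 2.42-fold and 2.22-fold higher, IGFBP3 was lower, and DOCK5 differed by -0.83. With probe sets averaged LATS2 and RBMS3 differed by 0.98 and 0.72, under 2-fold. The list's median was 0.021 (percentile 66.0) and -0.054 over the measurable members. NUPR1, a stress-induced chromatin protein, was 6.23-fold higher in the stress response list, where ATF3 was lower and ASNS and DDIT3 differed by 0.81 and 0.80 (list median 0.060, percentile 88.2). CFLAR, an inhibitor of caspase activation, was 2.24-fold higher in its brightest probe set, with its 12 measurable probe sets ranging from -0.57 to 1.24 and a mean over all of 0.50. BMF was 2.02-fold lower, TNFSF10 was 1.99-fold lower and PMAIP1 differed by 0.87; the median of the apoptosis regulators was 0.047 (percentile 76.5) and -0.047 without the _x_at and _s_at probe sets. The notch effector gene HES1 was 2.20-fold lower (-0.82 with probe sets averaged, and 0.059 without the _x_at and _s_at ones). LFNG, HES2 and DLL3 differed by -0.77, 0.63 and 0.41 (median of the notch list 0.053, percentile 68.3). No Wnt pathway gene of 19 was 2-fold apart, with DKK1, WNT7A, WNT7B and FZD6 at -0.98, 0.91, -0.72 and -0.64 and a median of 0.00 (percentile 28.7). With the arrays centred on their medians DKK1 was 2.01-fold lower. ALDH1A1, an aldehyde dehydrogenase used as a stem cell marker, was 4.93-fold higher from below the level. CD44, ABCG2 and CD24 differed by 0.87, -0.70 and 0.51, and the measurable probe sets of CD44 ranged from -0.14 to 1.30. The median of the stemness list was 0.013 (percentile 41.3), and below 0 under 4 of the settings. The cancer-testis genes MAGEA11 and MAGEB2 were 6.99-fold and 4.92-fold lower, and SSX1 and MAGEC2 differed by -0.46 and -0.27, SSX1 with the other sign when probe sets were averaged; the median was -0.099 (percentile 2.63).

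Ribosomal protein genes had a median of 0.013 (percentile 69.8), or -0.014 with the arrays centred on their medians, with none of 38 genes 2-fold apart, and the largest of them, RPL3, RPL6, RPL24 and RPLP2, differed by 0.14, -0.12, -0.12 and 0.10, RPLP2 with the other sign when probe sets were averaged. Reference genes had a median of 0.012 (percentile 63.2; -0.015 with the arrays centred, -0.068 without the _x_at and _s_at probe sets) with none of 22 genes 2-fold apart, and TFRC, SDHA, POLR2A and CHMP2A differed by -0.60, 0.51, -0.49 and 0.40, POLR2A with the other sign when probe sets were averaged. Of the endothelial markers only CDH5 (3.45-fold lower, below the level in the resistant array) and PECAM1 (-0.37) were measurable, and of the melanocyte markers PMEL (0.37), MITF (-0.30) and SOX10 (0.23). The medians of these lists over all measured members were 0.19 (percentile 96.9) and 0.15 (percentile 87.0), and that of the endothelial markers was -1.08 over the measurable members.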

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

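The probe sets that carry no gene symbol were not used in any comparison, and some of them held signal above the parental array. Of 3731 such probe sets at or above the level, 71 were at least 2-fold higher in the resistant array and 88 at least 2-fold lower. Probe sets with several gene symbols, likewise unused, added 25 higher and 17 lower among 1181. Their transcripts were not identified, and no explanation was tested.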

How the results depend on the processing

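With 1 array per group, no array could be left out and no test lost or gained a call; depth here is signal over background, and 7127 of 19775 genes lay below the level on both arrays. No paired analysis was possible because each group has 1 array. The count of lower genes (278) was 181 with all probe sets of a gene averaged, 170 with the level at the 75th percentile and 108 at a difference of 1.5, and that of higher genes (227) was 79 at a difference of 1.5; the other settings stayed within 1.5 times of both counts. The share of higher genes among all counted stayed between 41.8% and 48.2%. Centring the arrays or subtracting a lowess curve moved none of the 43 list medians by more than 1 SD of random lists. All 14 lists outside the random range stayed outside it under both. Centring shifts a list and its random lists by the same amount, so it could not change this. The lowess curve follows the mean, on which the random lists are matched, so it could change this little. With probe sets averaged 13 of these 14 stayed outside (heat shock genes did not), and without _x_at and _s_at probe sets 13 did (interferon-stimulated genes did not). With probe sets averaged, medians became 0.056 for RAS, RAF and PI3K genes, 0.45 for mesenchymal markers, 0.072 for matrix proteases, -0.18 for DNA replication, 0.39 for NF-kB cytokines, 0.12 for YAP and TAZ targets, 0.46 for cholesterol synthesis, -0.10 for heat shock and -0.35 for immediate early genes. Without _x_at and _s_at probe sets they became 0.048 for IGF binding proteins, 0.43 for mesenchymal markers, 0.14 for squamous differentiation, -0.30 for simple keratins, 0.20 for CDK inhibitors and p53 targets, 0.059 for interferon-stimulated genes, 0.21 for antigen presentation, 0.36 for NF-kB cytokines, -0.059 for Wnt genes, -0.054 for YAP and TAZ targets, -0.49 for drug transporters, -0.16 for hypoxia and glycolysis, 0.21 for stress response, -0.42 for heat shock, -0.047 for apoptosis regulators and -0.068 for reference genes. With measurable members only they became -0.21 for ERBB genes, 0.23 for other receptor kinases, 0.54 for antigen presentation, 1.03 for NF-kB cytokines, -0.054 for YAP and TAZ targets, -0.43 for drug transporters, 0.090 for fibroblast and -1.08 for endothelial markers. The median took the other sign under 1 or more settings in 10 lists, none of them outside the random range: ERBB genes, EGFR regulators, simple keratins, stemness markers, YAP and TAZ targets, apoptosis regulators, fibroblast and endothelial markers, ribosomal protein genes and reference genes; the cause was not tested. Of 213 named genes, 63 moved by more than the SD between probe sets when these were averaged, COL6A1 from 4.08 to 0.92 among them, and 8 took the other sign, of which 0 were 2-fold apart; of the 110 that were 2-fold apart, 21 were then under 2-fold; with a lowess curve subtracted 0 moved, and ERBB3 took the other sign. For 6 of these 213 genes, and for IL6, which is not among them, a scaling moved the difference across the 2-fold line. Each moved by less than 0.27, the SD between probe sets. Centring the arrays took HLA-DMA from 1.01 to 0.99 and IL15 from 1.01 to 0.98, and DKK1 from 1.97-fold to 2.01-fold lower and TNFSF10 from 1.99-fold to 2.03-fold lower; in the NF-kB list it left 13 of the 14 genes 2-fold higher, with IL6 going from 1.02 to 0.99. The lowess curve took BMP4 from -1.02 to -0.99 and PDGFA from 0.99 to 1.01. Without the _x_at and _s_at probe sets, 24 of the 110 genes were not measured and 12 were under 2-fold: S100A8 (0.62), ROR1 (-0.081), FAS (0.56), GDF15 (-0.31), HES1 (0.059), SMAD6 (0.33), AKR1C2 (-0.13), ABCC3 (-0.54), CFLAR (-0.57), LUM (0.061), MT1G (0.075) and IL1RL1 (-0.16).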

Other observations

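The gene groups and tests in this part were chosen after the result was seen, except the test of the gene run without shared name stems. When the measurable genes were grouped by the letters that start their symbol, 214 stems with 8 or more genes could be compared with 1000 matched random lists each. Of these stems 16 lay below and 8 above the central 95% of random lists, where 10.7 would lie outside it by chance if stems were independent. The MT, IL and HLA stems lay above every random list, the HLA genes with a median of 0.42. HLA-B, HLA-C, HLA-E, HLA-F, HLA-G and HLA-J differed by 0.40 to 0.84, each read by an _x_at probe set. They share sequence and so do not count as 6 separate observations. HLA-DMA differed by 1.01, while HLA-DMB, HLA-DOA, HLA-DOB and HLA-DQB1 differed by -0.12, -0.096, 0.27 and 0.13. HLA-F-AS1, also under this stem, differed by 0.00. Of the 9 MT genes, 8 were grouped as metallothioneins, small zinc- and copper-binding proteins. The other was the metallothionein-like gene MT1HL1, which differed by 1.30. MT1E, MT1F, MT1G, MT1H, MT1X and MT2A were 2.20 to 3.16-fold higher in the resistant array, while MT3 and MT4, near the level on both arrays, differed by 0.00 and -0.040; the first 6 are closely similar in sequence and were read by _x_at probe sets, so they do not count as 6 separate observations. Genes whose symbols start with IL had 10 of 42 members at least 2-fold higher and 1 lower, with a median of 0.20 above every random list. Of these 10, 5 also belong to the NF-kB list, and the others were IL20RB (5.08-fold), IL33 (4.65-fold) and IL22RA1 (3.30-fold), each from below the level, IL17RD (2.60-fold) and IL15 (2.01-fold), and the receptor gene IL1RL1 was 2.11-fold lower. With probe sets averaged MT1G, IL17RD and IL1RL1 were under 2-fold, at 0.60, 0.84 and -0.33. Without the _x_at and _s_at probe sets MT1G and IL1RL1 differed by 0.075 and -0.16, and the other 5 of the 6 metallothioneins and IL15 were not measured. With the arrays centred on their medians 8 of the 42 were 2-fold higher, with IL6 and IL15 at 0.99 and 0.98, and the medians of the metallothioneins and of the IL, HLA, SRSF, DDX, DNAJC, PSMD, NOL and RBM genes kept their sign under both scalings.

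The stems at percentile 0.30 or under were DDX, SRSF, DNAJC, NOL, PSMD and RBM, each lower by a small amount. All 9 measurable SRSF splicing factor genes were below the parental value, from SRSF4 at -0.051 to SRSF10 at -0.89, with a median of -0.38 (percentile 0.10). Of 31 DDX genes, most of them RNA helicases, 23 were below it, with a median of -0.31 under every random list, and DDX52 was 2.09-fold lower (-0.72 with probe sets averaged). The medians of the DNAJC, NOL and RBM genes were -0.21, -0.44 and -0.18. The 13 genes whose symbols start with PSMD, most of them subunits of the proteasome cap, had a median of -0.34 (percentile 0.30).

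The 14 NF-kB-linked genes that were 2-fold higher form a pattern for which technical explanations were weighed. Leukocytes in the resistant culture would bring their abundant transcripts, but the highest difference among 13 leukocyte markers was 0.34 (CD79A), with TYROBP at 2.89 on both arrays. A brightness-dependent bias would shift random lists of the same brightness, and the upper end of the central 95% of their medians was 0.12 against 0.47. The list stood out by this same comparison, so it is no separate test. With a lowess curve of the difference on the mean subtracted, the list's median was 0.48 and 14 members were 2-fold higher. Cross-hybridisation stays open. In 100% of the 5 members with 2 or more measurable probe sets, all probe sets were higher. Among all 2-fold higher genes with 2 or more measurable probe sets this held for 90 of 100. It was thus likely in advance for any such gene and does not decide the question. The other 9 members had 1 measurable probe set. What also remains open, and untested, is whether the difference belongs to the resistance, to long passage, to the antibody in the medium or to the state of the single culture sampled.

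A second pattern is a run of neighbouring genes with lower values, which has no settled explanation. Along the gene order of GRCh38.p14, the 40 measurable genes from LRRC8C to EXTL2 had a median of -0.40 (1.32-fold lower) and 31 of them were below the parental value; 0% of 1000 random gene orders held a window as low, which argues against a chance order. The 5 genes directly before it, GBP3, GBP1, GBP2, GBP4 and GBP5, were all higher (0.13, 0.27, 0.54, 0.80 and 1.12), while the 200 genes before it had a median of -0.20 and the 200 after it -0.024. Lower values were not confined to the run: every 40-gene window centred on a gene from RPL22 to PSMA5 had a median below 0. The 200 genes after the run pool windows as low as -0.30 (around AP4B1) with later ones up to 0.092 (around ACP6). Their median therefore does not show where the lower values end. Whether fewer DNA copies or a co-regulated gene family lie behind it stays open. The 20 genes on each side had a lower median, as a wider loss of copies would give (-0.20 together, -0.17 before and -0.25 after). The 2.5th percentile for random sets of 40 genes was -0.11. On each side 13 genes were lower, against 7 higher before the window and 5 higher after it. The lower medians had been seen before the prediction was written and so do not decide it. For a gene family, the window was picked for its low median, and the 29 genes without a shared name stem (median -0.42) had to stay near the median of the window, so that the prediction written for that test was no real bound. With 60 genes per window the lowest window (-0.33) held all 40 of these genes. With a lowess curve subtracted it was the same 40 genes at -0.38. With 20 genes it was another one (-0.46), from PHTF1 to WDR3, further along the same chromosome. At 40 genes per window, 18 windows spanning 58 genes from GBP5 to TAF13 lay below every random order.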
